A study of Mus musculus with 2 samples.

How the data were processed

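RNA sequencing data of 2 libraries were used, 1 from mock-treated and 1 from anti-CD3e and anti-CD28 treated splenic CD4+ T cells of male C57BL/6JJcl mice, each from cells pooled from 4 spleens. Total RNA was the starting material and the antibodies were given for 4 h, per the labels' protocols. Mean insert sizes were 211.79 bp for the mock library and 199.014 bp for the stimulated library, per the labels' protocols. The deposited files list splice junctions in BED format, and the score column holds counts of reads that span each junction, which were used as deposited, with no normalization. The submitters' processing notes name TopHat, an aligner that finds junctions, Cufflinks and the genome build mm9; their versions, settings and any filter on junctions are not given in the sources used here. An aligner that drops or moves a junction in 1 library changes that junction's count, and reads inside an exon are not counted, so a gene's value depends on how many junctions it has and on how well they were found. Gene-level values from the authors were not used here.

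The annotation given was GENCODE release M21 on GRCm38, another build than mm9, and no coordinate was converted between them. Positions were compared: 1.98% of the junctions equalled a GRCm38 intron, and on 8 chromosomes junctions lay past the last annotated gene. Genes were therefore named by structure. A junction took the name of a gene when it had the same chromosome, strand and intron length as an annotated intron and its exact distance to at least 1 other such junction equalled the distance between those introns in a transcript of that gene. Of 124183 junctions 95511 (76.9%) got a name, 245 fitted more than 1 gene and were left out, and 28427 got none; 9701 genes were named. When chromosomes were exchanged in 21 rotations as decoys, 6 junctions were named on average and 12 at most. The shift between builds was within 1000 bp of that of a neighbouring gene for 99.95% of named genes. Tested on simulated data of 1000 genes, the match named 97.8% of junctions, all with the right gene. Genes with 1 intron cannot be named in this way, nor can genes without introns, so Jun, Junb, Egr1 and S1pr1 among others have no value. Some genes with more introns had no named junction either, among them Gapdh, Pgk1, Hsp90aa1 and Rpl3, and the cause was not tested. All positions are given in mm9, from 1.

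A gene's value was the sum of its named junction counts per 1000000 junction reads of the library. The ratio of the stimulated to the mock value was given with an exact 95% interval from the binomial distribution of the stimulated reads among both. A gene with at least 20 reads over both libraries, a ratio of at least 2 or at most its inverse, and an interval that excluded 1 was called higher or lower. Where a library had 0 reads, the ratio was computed against 3 reads in that library and is a bound for that number of reads, and the text gives the limit of the exact 95% interval beside it. No p-value was computed, because with 1 library per group there is no measure of the spread between samples. The spread between junctions of the same gene, over 4919 genes with 3 or more junctions of at least 10 reads, was 2.02 times the counting variance.

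Before the data were examined, 35 gene lists were fixed, together with the groups, the thresholds, the rule for the genes named in the text and most of the other settings tried. The rule named the 12 genes with the highest lower limit and the 12 with the lowest upper limit of the interval, the members with the highest, lowest and most reads of every list, a set of T cell genes, the 10 largest differences in splice site use, and the 5 most-read junctions of each unmatched or single-library kind. Cybb, the gene families and other members of lists were chosen after gene values were seen. A list's median log2 ratio was placed among 10000 random lists of the same size, drawn within 20 bins of mean expression, and the percentile describes these 2 libraries only. Lists with fewer than 3 measured members have no median. A few results that the rule names are not reported here. Immunoglobulin genes, receptor segment genes and genes with near-identical copies are given as uncertain.

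A splice site was tested when it was shared by more than 1 junction and had at least 20 reads in each library. It was counted when a junction's share of its reads differed by at least 20 percentage points and the exact 95% intervals did not overlap. The count expected from sampling came from 1000 draws with both libraries at the pooled share, and again with their variance widened to that between junctions of a gene, a test added after seeing the data. For junctions seen in 1 library only, at least 10 reads were needed.

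The settings fixed then were scaling by the median of ratios, by the trimmed mean of M values and by the total without the 20 most-read genes; other read minimums; a fold of 4; the most-read junction or the median over junctions as the gene value; junctions with overhangs of at least 20 bp or seen in both libraries; thinning to equal reads; and other limits for splice sites. Settings added after seeing the data were intervals widened by the spread between junctions, leaving out each gene's most-read junction, removing a trend on GC content, and using only splice sites of matched junctions of 1 gene. The steps were tested on simulated counts of 7187 genes, drawn with counting error only. The calls among unchanged genes and unmoved sites therefore leave out the wider spread between junctions. With that spread, draws without a difference gave a mean of 42.4 splice sites. All 50 genes simulated 8-fold higher and all 46 simulated 8-fold lower were called, as were 45 of 50 (90%) at 3-fold higher and 45 of 46 (97.8%) at 3-fold lower, and 55 of 6995 unchanged genes (0.786%) were called. Of 50 splice sites with a moved share 48 (96%) were found, and of 4233 unmoved sites 2 were. Of 200 unchanged lists 7 (3.5%) lay in the outer 5%. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.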

Results

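Spliced RNA was compared between resting and stimulated mouse CD4+ T cells, the helper lymphocytes of the immune system. Cells pooled from 4 spleens of male C57BL/6JJcl mice were enriched magnetically. They were then held for 4 h on immobilised antibodies to CD3e, a chain of the T cell receptor complex, and to the costimulatory receptor CD28, each coated at 2 ug/ml, or held in the same way with no antibody. The question, as far as the title of the series gives it, was which changes come early when these cells are activated. 1 library was sequenced per group, so there was no replicate check, and every difference reported here is a difference between the mock library and the stimulated library. The values are counts of reads that cross a splice junction. The mock library held 1147232 such reads on 97850 junctions and the stimulated library 1341197 reads on 97395 junctions. All intervals are exact (Clopper-Pearson) 95% intervals that cover counting error only, and reads are not independent molecules. A gene with 0 reads could still have been present at up to 2.61 reads per 1000000 junction reads in the mock library and 2.24 in the stimulated library.

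Genes for cytokines, early transcription factors and ribosome building had more junction reads in the stimulated library, and genes of the naive, resting state had fewer, while genes of T cell receptor signalling went both ways. Il2, which encodes the growth factor interleukin 2, went from 0 to 92 reads. It was 26.2-fold higher when set against 3 reads, with a lower limit of 20.9 from its interval. Il2ra, a chain of its receptor, went from 73 to 1537 reads (a log2 ratio of 4.17), and the growth regulator Myc was 23.2-fold higher (15.3 to 36.9). Il7r, the receptor for the survival cytokine interleukin 7, was 30.3-fold lower (24.0 to 38.9). All 41 measured members of a ribosome biogenesis list were higher in the stimulated library, with a median log2 ratio of 2.81, while none of 28 measured genes of naive and quiescent T cells were higher and 20 were lower.

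Of 7206 genes with at least 20 junction reads over both libraries, 1233 (17.1%) were at least 2-fold higher in the stimulated library with an interval that excluded 1, 1806 (25.1%) were at least 2-fold lower, and 4167 met neither condition. These are the meanings of higher and lower for a gene throughout. Higher genes made up 40.6% of the 2 sets together when libraries were scaled by their total junction reads, and 52.5% (1555 higher, 1409 lower) when scaled by the trimmed mean of M values. The median log2 ratio of all measured genes was −0.21, and the trimmed mean put the point of no change at −0.24, so a gene or list with a small ratio can change sign with the scaling. Reads had been spread over many genes in both libraries: the 10 most-read genes held 4.67% of the mock reads and 4.72% of the stimulated reads.

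**Figure D1:**
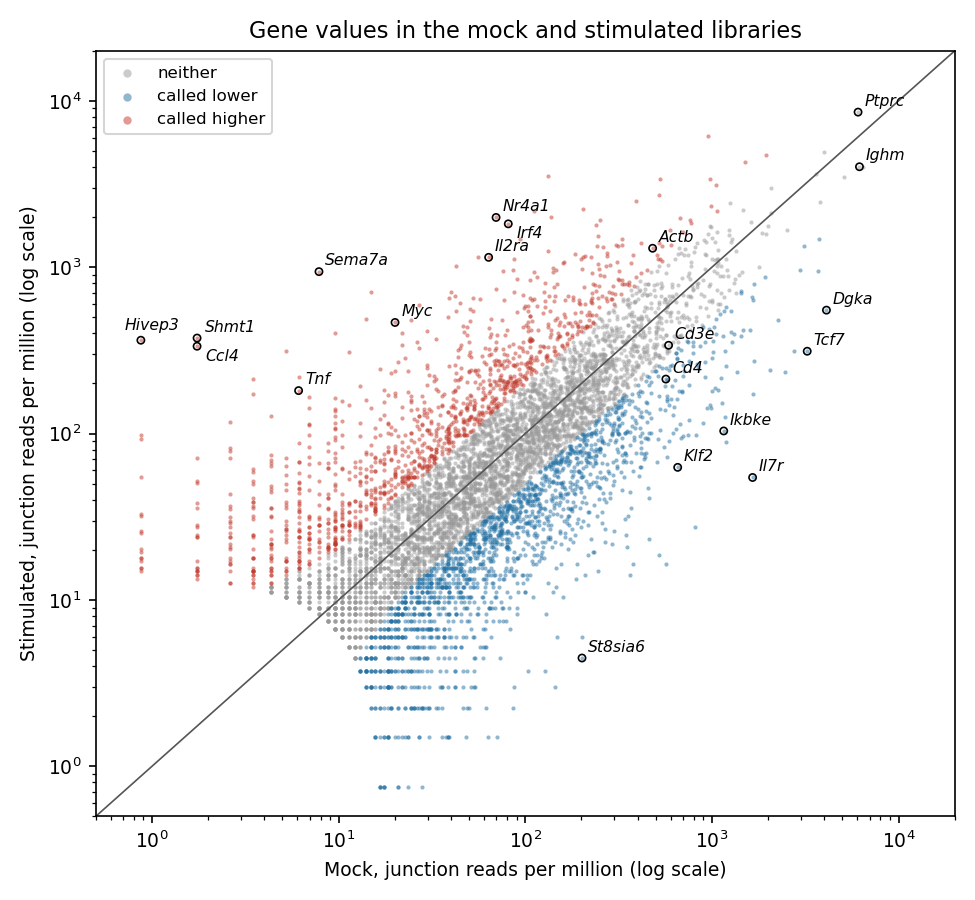
Junction reads per 1000000 of each measured gene in the mock library (horizontal axis, log scale) against the stimulated library (vertical axis, log scale), with 1 point per gene, red for higher, blue for lower and grey for neither; genes with 0 reads in a library are not drawn. Il2ra, Nr4a1 and Irf4 lie far above the diagonal and Il7r and Tcf7 far below it, while Ptprc, the most-read gene of the stimulated library at 0.855% of its reads, lies near it.

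By the limit of the interval nearest to no change, the genes that stood furthest above the mock library included regulators of transcription, secreted and surface signals, and enzymes. Hivep3, a zinc finger protein, went from 1 to 488 reads (417-fold, 74.6 to 16521). Sema7a, a membrane-bound semaphorin, was 120-fold higher (62.9 to 263), and Shmt1, an enzyme of folate-linked carbon transfer, went from 2 to 503 reads (215-fold, 59.2 to 1781). The chemokine gene Ccl4 went from 2 to 449 reads (192-fold, 52.9 to 1591). All 3 members of the orphan nuclear receptor family Nr4a were in this set: Nr4a2 was 48.1-fold, Nr4a1 28.5-fold and Nr4a3 26.6-fold higher. The others were Bcat1, which starts the breakdown of branched-chain amino acids, at 59.7-fold, Sh3bp2 at 60.9-fold, Irf8 at 42.1-fold, Srm, which makes spermidine, at 35.1-fold, and Il2. Hivep3 had a junction of 148 stimulated reads and no mock read, and without its junctions seen in 1 library only its log2 ratio was 6.33 in place of 8.71. With 1 mock read in the whole gene, leaving such junctions out lowers the ratio by construction. Counting the most-read junction alone gave log2 ratios of 5.40 for Hivep3 and 4.05 for Shmt1, both computed against 3 mock reads because that junction had none.

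The genes furthest below the mock library included Rapgef4 (166 to 4 reads, 48.5-fold lower, 18.6 to 180), St8sia6, a sialyltransferase (231 to 6 reads, a log2 ratio of −5.49), the gene model Gm14085 (34.8-fold lower), Fanci, a DNA repair gene (34.4-fold lower), Rflnb (33.6-fold lower), Il7r, Als2cl (28.0-fold lower), Selenop (25.8-fold lower), Arhgef18 (23.0-fold lower) and Ttyh3 (531 to 31 reads). Tgfbr3, a coreceptor for transforming growth factor beta, went from 58 reads to 0. It was 22.6-fold lower against 3 reads, with a limit of 17.8 from its interval. When only junctions seen in both libraries were counted, St8sia6 and Fanci had log2 ratios of −4.38 and −2.23 in place of −5.49 and −5.10. For genes with so few stimulated reads that setting moves the ratio toward no change by construction, so these values decide nothing. For Rapgef4 the most-read junction alone gave −3.03 in place of −5.60.

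Immediate early genes, which respond to receptor signals without new protein, were higher in 14 of 18 measured members, and 1 was lower. Their median log2 ratio was 2.74, above all of 10000 random lists of the same size and expression. Besides the Nr4a genes and Myc, Egr2 went from 0 to 36 reads (10.3-fold higher against 3 reads, with a lower limit of 7.93). Klf6 went the other way and was 5.07-fold lower, from 156 to 36 reads. Fos, with 32 and 56 reads, met neither condition (interval 0.953 to 2.39). Egr3 had 16 stimulated reads and no mock read, below the minimum, and Egr1 could not be named from its junctions.

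Cytokine genes were higher in 13 of 15 measured members and lower in none, with a median log2 ratio of 3.02 (percentile 100 among random lists). Tnf, the inflammatory cytokine tumour necrosis factor, had the highest ratio at 29.7-fold (14.2 to 74.6), from 7 to 243 reads. Ifng, which encodes interferon gamma, was 9.69-fold higher (3.05 to 49.3), from 3 to 34 reads, and Csf2 8.13-fold higher (1.96 to 71.9), from 2 to 19. Cd40lg, the helper signal to B cells, was 3.95-fold higher and Tgfb1, the member with the most reads, 2.88-fold higher. Ltb, at 1.03-fold, met neither condition. Il3 (0 and 9 reads) and Il4 (3 and 8 reads) were below the minimum. Among 6 measured chemokines 5 were higher and 1, Ccl5, was 3.36-fold lower (1.45 to 8.69); the median log2 ratio was 3.99. Cxcl9 and Cxcl10, with 0 and 3 mock reads against 46 and 58 stimulated reads, are interferon-induced and are also made by other cells of the spleen. Among the 4 measured myeloid genes beside them Csf2ra and Cybb were higher, and the macrophage gene Cd68 stood at 10 and 11 reads. Below the minimum, Lyz2 had 15 mock reads and 0 stimulated reads and Flt3 had 8 and 0. All members of the myeloid list together held 68 mock and 85 stimulated reads.

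Surface proteins known to appear or increase on activated T cells were higher in 16 of 23 measured members and lower in none, with a median log2 ratio of 1.46 (percentile 100). Slc7a5, the large amino acid transporter, led at 23.8-fold (17.9 to 32.3), and the early activation marker Cd69 was 12.5-fold higher (9.63 to 16.5). The costimulatory receptor gene Tnfrsf4 was 2.40-fold higher. Cd5 had the most reads and was 1.95-fold higher (1.79 to 2.12), just under the limit. Nt5e, the ectonucleotidase CD73, had the lowest ratio, 0.671 (0.533 to 0.843).

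Among 28 measured genes of naive and quiescent T cells, 20 were lower and none higher, with a median log2 ratio of −2.94, below every random list. Besides Il7r, the transcription factor genes Klf2, which keeps T cells quiescent, and Tcf7, which encodes TCF-1, were 10.5-fold (8.34 to 13.3) and 10.4-fold lower (9.37 to 11.5). The chemokine receptor gene Ccr7 was 4.13-fold lower (2.38 to 7.54), from 60 to 17 reads. Pdlim1 had the highest ratio of the list at 1.63-fold (0.719 to 3.91) and met neither condition. S1pr1 could not be named from its junctions. Genes of migration and adhesion were lower in 10 of 16 measured members and higher in 3, with a median log2 ratio of −1.33 (percentile 0.02). Itga6, an integrin chain, was 13.5-fold lower (9.20 to 20.4) and Dock2, which drives lymphocyte movement, 2.55-fold lower, while Rgs16 was 27.3-fold higher (15.8 to 51.7). Cytokine receptors and their signal carriers were lower in 11 of 22 measured members, among them Ifngr2 (6.82-fold) and the kinase Jak1 (3.10-fold), and higher in 5, among them the interleukin 12 receptor chain Il12rb1 (27.1-fold, 8.99 to 134). Their median lay at percentile 0.27 of the random lists.

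T cell receptor signalling genes moved both ways, with 7 of 31 measured members higher and 10 lower. Lcp2, the adaptor SLP-76, was 6.47-fold higher (5.94 to 7.05) and Themis, which tunes receptor signals, was 27.7-fold lower (9.09 to 137). Cd4 itself was 2.67-fold lower (2.32 to 3.08), from 650 to 285 reads. Cd3e and Cd28, the targets of the antibodies, had ratios of 0.579 (0.513 to 0.653) and 0.608 (0.440 to 0.837) and met neither condition. The list's median log2 ratio was −0.14 (percentile 27.0), and it was 0.10 under the trimmed mean of M values, with 7 higher and 7 lower. Calcium and NFAT genes were lower in 10 of 21 measured members and higher in 3, with a median of −0.99 (percentile 0.24). Dgka, the diacylglycerol kinase that dampens receptor signals, was 7.44-fold lower (6.89 to 8.05), and Nfatc1 was 3.26-fold higher (2.76 to 3.85). In the NF-kB pathway 11 of 24 measured members were higher and 5 lower, with a median of 0.84 (percentile 99.8, and 93.7 from the most-read junction of each gene). The subunit gene Nfkb1 was 6.44-fold and the inhibitor-like Nfkbid 20.6-fold higher, the kinase gene Ikbke was 11.2-fold lower, and the inhibitor Nfkbia, at 1.61-fold (1.39 to 1.87), met neither condition.

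Among transcription factors of T cell lineages 9 of 29 measured members were higher and 4 lower, with a median log2 ratio of 0.36 (percentile 97.0, and 71.1 at its lowest under the other settings tried). Irf4, which controls effector differentiation, was 22.5-fold higher (18.3 to 27.9), Irf8 was the highest, and Batf, from 17 to 6 reads, was the lowest at 3.31-fold lower (1.25 to 10.3), a difference not kept with intervals widened by the spread between junctions. Genes of the interferon response were higher in 8 of 20 measured members and lower in 3, with a median of 0.87 (percentile 99.9). Gbp2 was 5.67-fold and Irf1 2.68-fold higher, and Irf7 was 2.71-fold lower. Under the trimmed mean the counts of this list were 11 and 1.

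**Figure D2:**
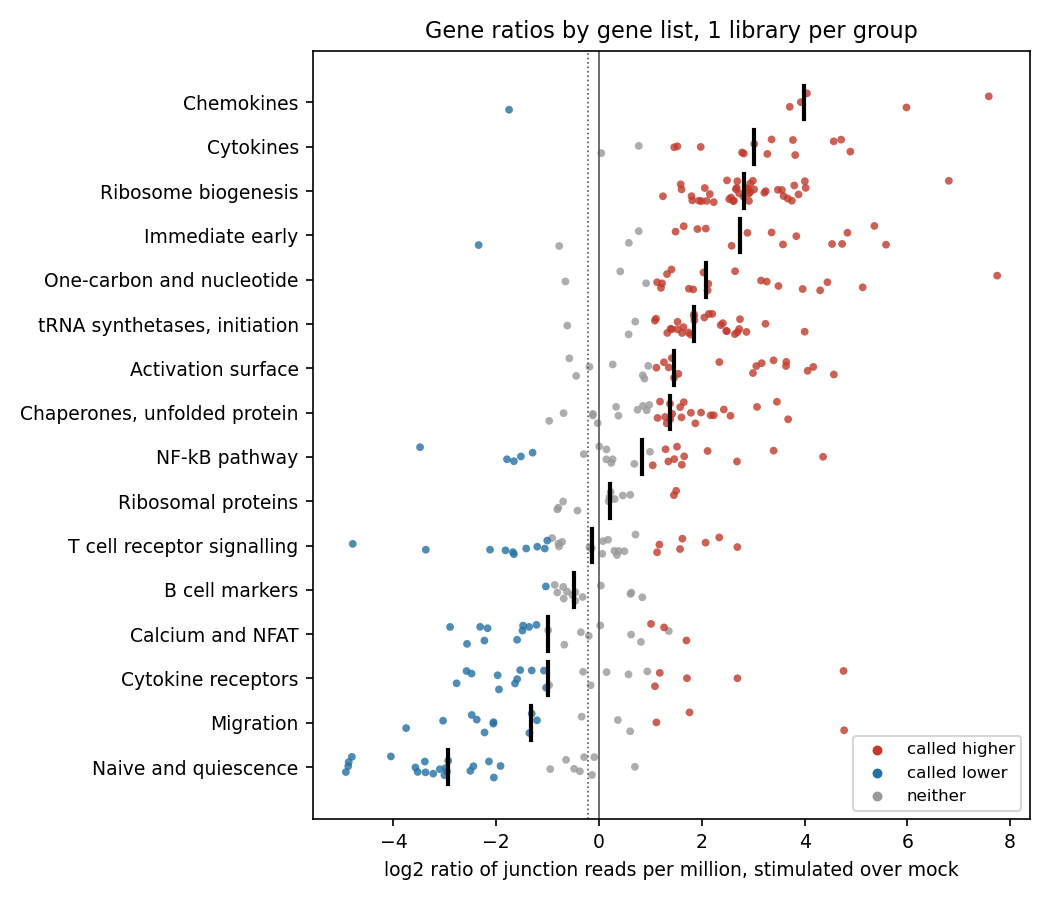
Log2 ratio of junction reads per 1000000, stimulated over mock (horizontal axis), for the measured members of 16 gene lists, with 1 point per gene, a black bar at each list's median, a solid line at 0 and a dotted line at the median of all measured genes (−0.21); genes at 0 reads in a library are drawn at their bound. The median is 2.81 for ribosome biogenesis, with every member to the right of 0, and −2.94 for genes of naive and quiescent T cells.

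Genes that build ribosomes, charge transfer RNA and make building blocks were mostly higher. Most of the 12 measured ribosomal protein genes met neither condition. In the ribosome biogenesis list the members ran from Ddx10 at 2.37-fold (1.92 to 2.95) to Bysl, which went from 1 to 131 reads (112-fold, 19.8 to 4459). Ncl, which encodes the abundant nucleolar protein nucleolin, was 3.49-fold higher (3.27 to 3.73). The list's median log2 ratio was 2.81 (percentile 100), and all 41 members were higher under each scaling tried. Transfer RNA synthetases and translation initiation factors were higher in 28 of 31 members and lower in none, with a median of 1.85 (percentile 100). Eif4ebp1, a repressor of cap-dependent initiation, led at 16.0-fold, Eif3c was 5.17-fold higher, and Qars, the glutamine enzyme, stood at 0.653 (0.571 to 0.745). One-carbon and nucleotide synthesis genes were higher in 19 of 22 members and lower in none, with a median of 2.07 (percentile 100). Shmt2, the mitochondrial partner of Shmt1, was 11.3-fold higher, and Prps2 stood at 0.637 (0.390 to 1.03). Of 40 listed ribosomal protein genes only 12 were measured, and of these 2 were higher and none lower, with a median of 0.22 (percentile 71.4). Rpl3, Rps6 and others had no named junction, and Rplp0 had 3 and 4 reads. The result therefore covers a smaller part of this family. Rps24 stood at 0.570 (0.202 to 1.52). Rpl8 was 2.83-fold higher, and its log2 ratio was 1.19 without a junction that had 1127 stimulated reads and no mock read.

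Chaperones and genes of the unfolded protein response were higher in 20 of 31 measured members and lower in none (median log2 ratio 1.38, percentile 100). Hsp90ab1, an abundant cytosolic chaperone, was 2.44-fold higher, Chac1 went from 0 to 45 reads, and Pdia3 stood at 0.511 (0.466 to 0.560). Proteasome genes were higher in 12 of 32 and lower in none (0.77, percentile 99.96), from Psma1 at 0.936 (0.790 to 1.11) to Psme3 at 5.65-fold. Genes of oxidative phosphorylation were higher in 10 of 35 and lower in none (0.31, percentile 98.5, and 94.7 without the most-read junction of each gene). Atp5b, a subunit of ATP synthase, stood at 1.80-fold and Sdhc at 0.530, and Atp5g1 went from 3 to 49 reads (interval 4.51 to 70.1). In glycolysis 7 of 15 measured members were higher and 3 lower (0.83, percentile 99.5). Gapdh, Pgk1 and Pgam1 had no named junction, and Eno1, Tpi1 and Ldhb were below the minimum. The hexokinase gene Hk2 went from 1 to 44 reads (37.6-fold, 6.41 to 1520), Aldoa stood at 1.78-fold, and Pdk1, which holds pyruvate back from the mitochondria, was 7.63-fold lower. Among cholesterol and lipid genes 5 of 19 were higher and 6 lower (0.36, percentile 96.4). Fasn and Acaca, which make fatty acids, were 3.79-fold and 4.99-fold higher. The cholesterol exporter Abca1 was 8.91-fold lower (4.25 to 21.6). Its log2 ratio was −1.23 where only junctions seen in both libraries count, a setting that moves such a gene toward no change by construction.

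Cell cycle genes did not share a direction. In the list for the G1 phase 4 of 13 members were higher and 4 lower (median log2 ratio −0.23, percentile 48.2, and 0.01 under the trimmed mean). The inhibitor gene Cdkn1a went from 0 to 49 reads, Rbl2 was 7.21-fold lower, and Ccnl1 stood at 0.891 (0.787 to 1.01). For DNA replication and mitosis 5 of 17 were lower and none higher (−0.34, percentile 38.8, and −0.98, percentile 7.20, from the most-read junction of each gene). Under the trimmed mean and under the median of ratios 3 were lower. Bub1b was 4.16-fold lower (1.94 to 9.90), Mcm6 stood at 0.790 and Tpx2 had an interval of 0.546 to 1.66. In the apoptosis list 3 of 17 were higher and 3 lower (0.14, percentile 86.2, and −0.06 without the most-read junction of each gene), with Gadd45b 9.56-fold higher, the initiator caspase gene Casp8 2.62-fold lower, and Trp53 at 1.10-fold. Autophagy and lysosome genes were lower in 5 of 17 and higher in 1, and under the trimmed mean lower in 3 and higher in 1. Their median was −0.53 (percentile 19.0), and −0.92 (percentile 1.73) from the most-read junction of each gene. Their regulator Tfeb went from 55 to 2 reads (32.1-fold lower, 8.49 to 272), Sqstm1 stood at 0.797, and Atg5 was 2.05-fold higher (1.20 to 3.65, and 0.942 to 4.84 when widened by the spread between junctions).

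Splicing factor genes were higher in 14 of 43 measured members and lower in 1 (median log2 ratio 0.69, percentile 99.9, and 0.24, percentile 91.05, without the most-read junction of each gene). Hnrnpa1 was 3.95-fold higher (2.87 to 5.54), Celf2 was 2.28-fold lower (1.88 to 2.77), and Sf3b1, with the most reads, stood at 0.659. Under the trimmed mean 18 were higher and none lower, so Celf2 then met neither condition. Chromatin modifiers were higher in 6 of 27 and lower in 5, with a median of −0.00 that became 0.23 under the trimmed mean (percentile 61.0). Kdm6b, a histone demethylase, was 14.6-fold higher (12.4 to 17.2), Hdac5 4.25-fold lower, and Chd4 stood at 1.93-fold. Regulators of RNA decay were higher in 2 of 20 and lower in 2 (−0.12, percentile 46.5). Under the trimmed mean 5 were higher and 2 lower, with a median of 0.12. Ago2 was 2.53-fold higher, Tnrc6b 2.95-fold lower, and Smg1 stood at 0.867. The list of genes known for regulated splicing in T cells held 53 genes, 47 of them also in other lists. Of its 50 measured members 18 were higher and 8 lower (0.41, percentile 98.7, and 93.1 without the most-read junction of each gene). Actb, often used as a reference gene, was 2.70-fold higher (2.45 to 2.98) and was higher under every scaling tried. At 1 of its junctions the stimulated library held 246 reads and the mock library none, and without it its log2 ratio was 1.21 in place of 1.43. The mock library held 162 reads on a copy of that junction shifted by up to 10 bp. Whether the mock value of Actb counts them was not tested, so its ratio may be too high.

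Transcripts of other cell types were present in both libraries. Ighm, the immunoglobulin heavy chain gene of B cells, had 7082 mock and 5386 stimulated reads, a ratio of 0.651 (0.628 to 0.674), and is uncertain because immunoglobulin genes are rearranged. Of 14 measured B cell markers none were higher and 1, Blk, was lower at 2.05-fold (median log2 ratio −0.49, percentile 23.7, and −0.06, percentile 62.3, without the most-read junction of each gene). Under the trimmed mean Blk met neither condition and H2-Ab1, with 51 and 107 reads, was the 1 higher marker. Of 4 measured myeloid and dendritic cell genes 2 were higher (0.91, percentile 92.8, and −0.05 with members down to 5 reads), namely Csf2ra, from 5 to 27 reads, and Cybb, from 5 to 19 reads. Natural killer and cytotoxic genes were lower in 4 of 6 and higher in 1 (−1.24, percentile 5.15, and −0.34, percentile 54.8, with members down to 5 reads), and 3 were lower under the trimmed mean. Crtam, which activated T cells also make, went from 2 to 48 reads (20.5-fold, 5.38 to 174), Cd7 was 7.55-fold lower and Ctsw 2.52-fold lower. The single measured neutrophil gene, Mpo, had 45 reads in each library. The haemoglobin gene Hbb-bs had 71 and 151 reads and Itga2b 16 and 8, and neither was higher or lower, though Hbb-bs was higher under the trimmed mean and under the median of ratios. Pecam1, an endothelial gene that leukocytes also express, was 6.07-fold lower (4.88 to 7.63).

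The counts of higher and lower genes rest on 1 library each and on counting error. The spread between junctions of a gene was 2.02 times the counting variance, and intervals widened by it left 1126 genes higher and 1607 lower. Of the higher or lower genes named here, Batf, Atg5, Blk and Cybb met neither condition with them. That widening used 1 factor for all genes, and the junctions of some named genes spread further. With 1 junction left out at a time, the standard error was 1.70 for Acaca, at a log2 ratio of 2.32. It was 1.69 for Csf2ra (log2 ratio 2.21) and 1.34 for Ifng (3.28). Other named genes can therefore be sensitive to this spread too.

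The value of other named genes moved by more than 1.5 times in at least 1 setting for the junctions counted. Il2, Egr2, Chac1 and Cdkn1a had 0 mock reads, so their values below follow from the reads taken for that library and are not measured ratios. With fewer junctions counted, fewer stimulated reads were set against the same 3 mock reads. The median over junctions instead added a fraction of a read to each library. Genes with few mock reads can meet the same limit where the junctions counted had none. Nearest to no change, the log2 ratios were 3.14 for Il2, 3.92 for Tnf, 2.76 for Cd69, 2.71 for Egr2, 6.59 for Ccl4, 4.78 for Irf8, 3.32 for Crtam and 4.16 for Il12rb1. They were 5.76 for Sema7a, 4.77 for Bcat1, 4.61 for Sh3bp2, 4.71 for Bysl, 1.36 for Acaca, 3.23 for Hk2, 2.44 for Atp5g1, 3.27 for Eif4ebp1, 3.05 for Chac1, 2.49 for Gadd45b and 1.31 for Hnrnpa1. Among lower genes they were −3.66 for Als2cl, −4.50 for Gm14085, −2.86 for Itga6, −3.55 for Themis, −3.81 for Tfeb and −2.17 for Cd7. Further from no change lay Irf4 at 5.52, Ifng at 4.10, Cdkn1a at 5.33, Csf2ra at 4.02, Selenop at −5.79, Ttyh3 at −5.26, Hdac5 at −3.08, Tnrc6b at −2.58, Casp8 at −2.37 and Dock2 at −2.21. Of genes that met neither condition, Qars lay at −1.52, Pdia3 at −1.59, Mpo at −1.13 and Sdhc at −0.13, and Rps24, Tpx2 and Itga2b, all with few reads, at −1.58, −1.01 and −3.93. List medians that moved as far were 2.13 for immediate early genes, 1.91 for cytokines and 4.98 for chemokines without the most-read junction of each gene, and 2.94 for one-carbon and nucleotide genes, 1.63 for glycolysis and 1.01 for cholesterol and lipid genes from that junction alone.

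Ptprc was among the genes whose use of splice sites differed between the libraries. Ptprc encodes CD45, the receptor phosphatase whose alternative exons are known to be left out in activated and memory T cells. Its gene total was 1.41-fold higher (1.37 to 1.45) and met neither condition. At the donor at position 140022879 of chromosome 1 (mm9, minus strand), the junction to 140013603 leaves out 3 annotated exons of 129, 147 and 141 bp. It held 48 of 152 reads in the mock library (31.6%, 24.3 to 39.6) and 184 of 328 in the stimulated library (56.1%, 50.5 to 61.5). The junction from the same donor into the 147-bp exon held 55.9% and 36.0%. Read from the acceptor at 140013603, the skipping junction held 33.8% and 54.3%.

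**Figure D3:**
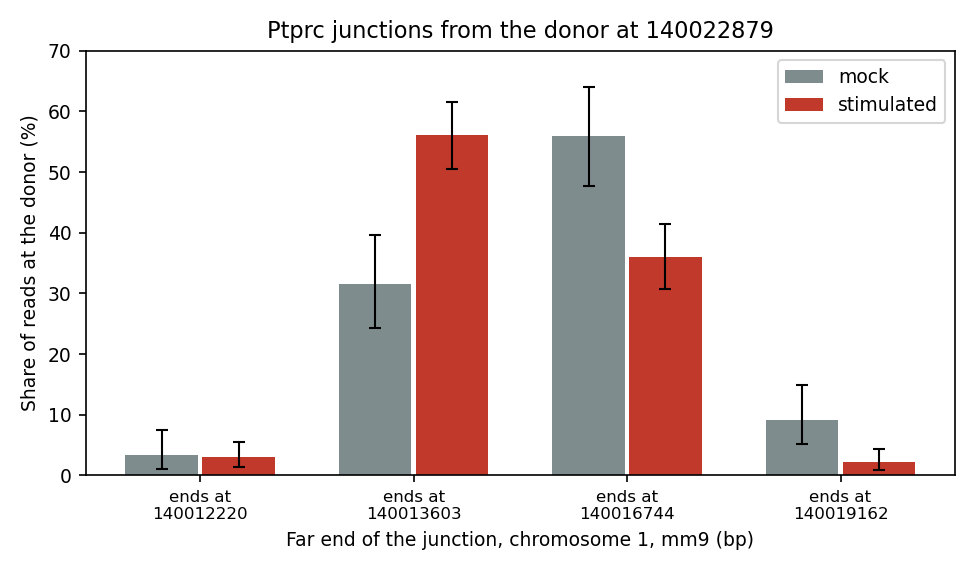
Share of the reads leaving the Ptprc donor at position 140022879 (vertical axis, percent) for junctions named to Ptprc, by the position of their far end on chromosome 1 in mm9 (horizontal axis), with grey bars for the mock library, red bars for the stimulated library and error bars for exact 95% intervals. The junction ending at 140013603, which skips 3 alternative exons, goes from 31.6% to 56.1%, and the junction ending at 140016744 goes from 55.9% to 36.0%.

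Of 4283 donor or acceptor sites with at least 20 reads in each library and more than 1 junction, 68 sites in 56 named genes (1.59%) had a junction whose share differed by at least 20 percentage points with intervals that did not overlap. Sampling alone, with both libraries at their pooled share, gave a mean of 2.62 such sites and at most 9 in 1000 draws. With the variance widened to the 2.02 times measured between junctions of a gene, draws without a difference gave a mean of 42.4 sites and at most 64, so many of the 68 sites can be scatter. With intervals widened in the same way 19 of the 68 sites kept the difference, both Ptprc sites among them. The 68 sites included 28 at which the longer junction skips an annotated exon, and its share was higher in the stimulated library at 17 of these and lower at 11. These sites are not independent. Some genes had more than 1, and in Ptprc, Zfp207 and Prrc2c the same junction was counted at its donor and at its acceptor. The 17 and 11 therefore do not show a lean toward skipping. Of the genes listed in advance for regulated splicing, 33 had a tested site and 3 had a differing site: Ptprc, Clk1 and Ikzf1. In Clk1, a kinase that acts on splicing factors, the junction that skips a 91-bp exon held 54 of 70 mock reads and 18 of 44 stimulated reads (77.1%, 65.6 to 86.3, against 40.9%, 26.3 to 56.8). In Ikzf1, the lymphoid transcription factor Ikaros, the longer of 2 junctions at an acceptor went from 3 of 66 reads (4.55%) to 30 of 119 (25.2%). With the widened intervals neither the Clk1 nor the Ikzf1 difference was kept.

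The largest differences in share, 1 per gene, were a mixed set, and with widened intervals those in Atxn2l, Spn, Dnm2, Srp54a and the Lime1 and Zgpat site were kept. In Rbm25, which encodes a splicing regulator, a junction that skips a 118-bp exon went from 17 of 21 to 12 of 41 reads. In Akap8l the junction that skips a 60-bp exon went from 7 of 36 to 13 of 20. In Vps54 the longer of 2 junctions, whose other end lies 36 bp away, went from 14 of 29 to 29 of 30, and in Prrc2c the shorter went from 19 of 27 to 6 of 27. In Atxn2l a junction went from 20 of 21 to 20 of 63 reads. In Spn, the surface sialoprotein CD43, a junction went from 113 of 200 to 25 of 289. In Dnm2 a junction at a site shared by 44 went from 65 of 92 to 20 of 83. In Zmat5 a junction 9 bp longer than its neighbour went from 0 of 21 to 13 of 22. Shares at Srp54a (53 of 53 to 9 of 27 reads) and at a site in Lime1 and Zgpat (9 of 42 to 39 of 49) are uncertain because of a near-identical copy and of overlapping genes. At 47 of the 68 sites a junction took part that matched no annotated intron, and 12 sites lay in near-identical copies or had no single gene name. Among 806 sites whose junctions were all matched, 21 differed, against a mean of 0.9 from sampling and 13.5 with the widened variance. Sites in near-identical copies were not left out of the 806 or of these means.

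Most junction reads lay on junctions that both libraries shared. The libraries together held 124183 junctions, of which 71062 were in both and carried 93.9% of the mock and 94.5% of the stimulated reads. A further 26788 were in the mock library alone and 26333 in the stimulated library alone, and 55.6% of these had 1 read. With at least 10 reads in 1 library and none in the other there were 948 junctions of the mock library and 1169 of the stimulated library. After the stimulated library was thinned to the depth of the mock library these counts were 1007 and 938, so which library had more turned with depth. The most-read such junctions of the stimulated library lay in Rpl8 (chromosome 15, 76734540 to 76734732, 1127 reads) and Actb (246 reads, with 162 mock reads on a shifted copy). Hivep3 (148), Gramd1b (131) and the T cell adaptor gene Lcp2 (116) followed. The most-read of the mock library included junctions in the lymphocyte GTPase gene Gimap4 (112 reads) and in St8sia6 (88 reads). Others lay at 108654511 to 108655609 of chromosome 7 and 141068471 to 141072427 of chromosome 5 (109 and 95 reads, no gene named).

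Named introns carried nearly all reads in both libraries. Junctions matched to the structure of an annotated gene made up 83.8% of the junctions and 95.6% of the reads in the mock library, and 81.8% and 96.0% in the stimulated library. Of the 28427 junctions without a match 64.1% had 1 read. Among the most-read were chromosome 1, 135974281 to 135975488 (859 and 639 reads), and chromosome 5, 125868635 to 125870066 (550 and 523 reads). The junction at 45707744 to 45707961 of chromosome 17 lies between the outermost named junctions of Hsp90ab1 and had 221 and 710 reads, a ratio of 2.75 (2.36 to 3.21). A pair on chromosome 12 start at 114660942, next to the named junctions of Ighm: the junction to 114666724 had a ratio of 0.657 (0.583 to 0.740), and that to 114667678 had 0.414 (0.365 to 0.471).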

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

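The test for shifted copies of a junction was chosen only after the junctions were seen. A signal appeared among junctions that no gene value uses: 117 junctions without a matched gene had at least 10 reads in the stimulated library and none in the mock library, against 54 the other way round. After thinning to equal reads these were 83 and 59, so part of the difference comes from depth. The most-read of them had 56 stimulated reads (chromosome 9, 40220960 to 40241792), 48 (chromosome 13, 30849631 to 30855395, whose upper end is also the end of the last named junction of Irf4) and 43 (chromosome 15, 74828048 to 74879214). A further signal in such data lay at position 54840195 of chromosome 14, the acceptor before the named junctions of Trac, the constant gene of the T cell receptor alpha chain. There, 30 unmatched junctions held 90 stimulated and 30 mock reads, a ratio of 2.57 (1.68 to 4.02). Receptor genes are rearranged differently in each cell, so single junctions at this site are uncertain.

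Junctions with at least 10 reads in 1 library and none in the other were weighed further, since leaving them out moved the ratios of Hivep3 and Rpl8. Among junctions of genes with reads elsewhere, 1427 were of this kind, 0.833 times the number that the ratio of each gene's other junctions gives with counting variance widened by the spread between junctions. That spread was estimated on the same junctions, and with counting variance alone the number seen was 4.06 times the number expected. Beyond the gene's own ratio stood 63 junctions in 63 genes, 35 without mock reads and 28 without stimulated reads, where 4.85 were expected. Tests argued against reads placed on a copy of the junction shifted by up to 10 bp, found at 4.76% of the 63 (0.993 to 13.3) against a needed 20%, though Actb was 1 of these 3, and against another junction at the same splice site, found at 1.59% (0.0402 to 8.53). What stays open is a loss of single junctions by the aligner, which may have struck either library, or a difference in the RNA itself, and neither was tested.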

How the results depend on the processing

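Alternatives chosen after seeing the data are the widened intervals, the removal of each gene's most-read junction, the removal of the GC trend and the restriction of splice sites to matched junctions of 1 gene. Among the genes that the naming rule chose, none called higher or lower changed direction in the settings run for it. Which of the libraries had more single-library junctions of at least 10 reads turned with equal depth. Whether more genes were lower or higher turned with the trimmed mean. The medians of T cell receptor signalling, G1 phase, chromatin and RNA decay genes changed sign with that scaling. The apoptosis median changed sign without the most-read junctions, and the myeloid median with a minimum of 5 reads. Of 222 comparisons of list medians 216 stayed within the range that resampling the list's own members gave and 6 moved. That range can be wide, as for natural killer and cytotoxic genes (−2.41 to 2.42). Staying within it therefore does not show that a list was stable. For single named genes 935 comparisons stayed and 153 moved. A 4-fold limit left 484 genes higher and 632 lower, by construction. Scaling by the median of ratios or the trimmed mean moved every median by the same amount, which for ribosome biogenesis gave 2.97 and 3.05 and for replication and mitosis −0.18 and −0.10. The most-read junction alone gave cholesterol and lipid genes a median of 1.01, and ribosomal proteins without it 0.71; the cause was not tested. With 20 reads needed, fewer junctions remained by construction, 189 mock-only and 360 stimulated-only. Whether the stimulated library keeps more of them at equal depth was not tested. Differing splice sites numbered 25 with 50 reads per site, 104 with 10 reads, 34 with 99% intervals, 19 with widened intervals and 21 at sites of matched junctions of 1 gene, since these settings test fewer or more sites or ask for more. Junctions with few reads matched least often: at 2 and 10 reads the matched share was 92.6% and 97.7% of mock junctions, 96.4% and 97.3% of mock reads, 91.9% and 97.5% of stimulated junctions, and 96.8% and 97.8% of stimulated reads, and at equal depth it was 83.1% of stimulated junctions. Gene values used only junctions matched in structure to an annotated intron, so restricting them to such junctions gave no separate value. Depth limits genes under about 20 reads, such as Il3, Il4 and Egr3. No paired analysis was possible because each group has 1 library.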

Other observations

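The gene families here, the tests of scaling, GC content and few abundant genes, and the test of B cell RNA were chosen only after gene values were seen. Several families outside the fixed lists had medians above nearly every random list, though most members of Mrpl, Mrps, Nup, Polr, Ddx and the pore carriers met neither condition. Mitochondrial import genes (Timm and Tomm) were higher in 8 of 12 measured members and lower in none, with a median log2 ratio of 1.60 (percentile 99.99). Among them Timm17a went from 0 to 73 reads (20.8-fold higher against 3 reads, with a lower limit of 16.5). Small mitochondrial ribosome proteins (Mrps) were higher in 10 of 23 and lower in 1 (0.96), and large ones (Mrpl) were higher in 13 of 36 and lower in 1 (0.70). Carriers through the nuclear pore (Ipo, Kpn and Xpo) were higher in 7 of 18 and lower in 1 (0.83). Ipo4 was 12.5-fold higher (10.1 to 15.8) and Xpo1 stood at 0.440 (0.371 to 0.521). Under the trimmed mean of M values 10 of the carriers were higher and none lower. Exosome genes (Exosc) were higher in 5 of 9 (1.04), Ddx helicases in 12 of 29 with 2 lower (0.62), RNA polymerase subunits (Polr) in 7 of 20 with 1 lower (0.66), and nucleoporins (Nup) in 4 of 17 with none lower (0.78, 9 under the trimmed mean of M values).

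Kinesins (Kif) were lower in 9 of 16 measured members and higher in 1, with a median log2 ratio of −1.18 (percentile 0.48). The exception, Kif15, went from 11 to 184 reads (14.3-fold, 7.81 to 29.2). The next families lay within the random lists. Zinc finger genes (Zfp) were lower in 22 of 89 and higher in 4 (−0.41, percentile 24.3, and 16 and 8 under the trimmed mean). Trim genes were lower in 9 of 21 and higher in 1 (−0.69, percentile 10.4, and 6 and 1 under the trimmed mean). Usp genes were lower in 8 of 37 and higher in 3 (−0.30, percentile 25.2, and 8 and 7 under the trimmed mean). Rab genes were lower in 4 of 26 and higher in 1 (−0.41, percentile 26.2, and 2 and 2 under the trimmed mean). Of 6 Gimap genes 2 were lower and 1 higher (−0.72), and under the trimmed mean none were lower. Solute carriers (Slc) split, with 26 of 109 higher and 27 lower (−0.12, and 0.11 under the trimmed mean); Slc19a1, the reduced folate carrier, went from 2 to 68 reads (29.1-fold, 7.75 to 245) and Slc28a2 from 264 to 26.

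Next to the named Ighm junctions, the site at 114660942 of chromosome 12 joined 26 unmatched junctions with 2724 mock and 1451 stimulated reads, a ratio of 0.456 (0.427 to 0.486). The mitochondrial chromosome held 15 junctions with 15 mock and 5 stimulated reads. Over 3832 genes the median share of junction reads in the upstream part of the gene was 41.3% in the mock and 42.2% in the stimulated library, a median difference of 1.12 percentage points.

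More genes were lower than higher in the stimulated library, and the explanations weighed were the scaling, a few abundant genes, GC content and the stimulation itself. The 10 most-read genes held 4.72% of the stimulated reads against 4.67% of the mock reads, which argues against a few genes that take reads from the others. With the genes in 5 bins of GC content the share of higher genes among higher and lower ones ran from 33.4% (29.8 to 37.2) in the highest bin to 45.8% (41.4 to 50.2) in the lowest, so the excess varied with GC content, and GC content stays open as a part of the cause. Removing a trend on GC content gave 40.8%, but the trend was centred on its median, which holds the balance near its place. Under the trimmed mean of M values the share was 52.5%, but that scaling centres the genes by construction, so the value decides nothing, and the scaling cannot be told apart from a true excess of lower genes after stimulation, as no measure of RNA per cell was used here.

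For Ptprc, a hypothesis is that stimulation for 4 h had already moved the splicing of CD45 toward the form without its alternative exons. A smaller share of B cell RNA, which keeps all of these exons, could give the same direction, but it leaves untouched the balance between the skipping junction and the junction from the same donor into the 147-bp exon, neither of which transcripts with all of these exons use. Among these 2 junctions the skipping share was 36.1% (27.9 to 44.9) in the mock and 60.9% (55.2 to 66.4) in the stimulated library, which argues against B cell RNA as the whole cause. The skipping junction had a ratio of 3.28, and 0 of 32 other Ptprc junctions with at least 50 reads reached it (median 1.51, 0.665 to 2.03). It had been picked for its gain in share at a differing site, which favours this outcome. The comparison therefore does not exclude scatter between junctions. A change in the mix of naive and memory T cells was not tested and stays open beside the stimulation.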
